A study of Mus musculus with 6 samples.

How the data were processed

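Gene expression was measured on 6 two-channel microarrays that carried total RNA of mouse testis, mouse epididymis and the stromal vascular fraction (SVF) of mouse fat, the mixed non-adipocyte cells of adipose tissue. The labels name Qiagen for the extraction and Ambion for the labelling of the RNA, and Cy3 and Cy5 as the dyes, with no further protocol. Each pair of tissues was hybridised on 2 arrays with the dyes exchanged, which gives 3 dye swaps that close a loop. The series names 3 RNA samples, so each tissue is represented by 1 RNA sample, and the 2 arrays of a dye swap are repeat hybridisations of the same RNAs.

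The deposited table holds 1 log ratio per probe and array for 25344 probes, and the authors' base of the logarithm, background correction, normalization and direction are not given in the sources used here. The deposited values were read as log2 ratios. Base 10 would exceed the range of a 16-bit scanner, and the choice of log2 over the natural logarithm is by convention, so the printed folds rest on it. As deposited, column medians were 0.005, 0.114, 0.044, 0.048, 0.007 and 0.01, and the extremes ran from -8.41 to 10.25. The numerator was taken as the Cy5 tissue, which each title names first. The dye-exchanged arrays of a pair correlated negatively across all probes as deposited, with Pearson's r of -0.86 for testis and SVF, -0.64 for epididymis and SVF, and -0.77 for epididymis and testis, so the ratio runs the same way by dye within each pair, and the sign of the exchanged array was turned. The overall direction is therefore likely rather than stated. With it, 30 of 32 measured late spermatid genes were higher in testis than in SVF and none was lower. Genes are not independent replicates in any correlation across genes given here.

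Probe names came from the platform annotation paired with the table, whose symbols can be old. It listed 21112 probes. Of these, 20456 were matched by gene ID to the mouse gene table of GRCm38.p6, 220 by symbol, and 259 kept the annotated name. Another 147 probes with non-mouse symbols and 30 probes with several genes were not named, and 4232 probes had no annotation row. The 20935 named probes gave 18550 genes. A gene's value was the mean over its probes, and 1629 genes had 2 or more probes. Probes of the same gene met the size rule in opposite directions for 48 genes in testis against SVF, 10 in epididymis against SVF and 38 in epididymis against testis. No coordinates are given because the annotation names no genome build.

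With 1 RNA sample per tissue there is no test between tissues, and no p-value is given for any gene. A gene was counted as higher in a tissue when its log2 ratio was at least 1 (2-fold) in the same direction on both arrays of the dye swap. Values are means of the 2 arrays ± SD (n = 2 hybridisations), an error that covers dye and hybridisation and leaves out differences between animals. Spot intensities and background flags were not analysed here, so it is not known which genes were above background in a tissue. Depending on the background correction, which is not given, a signal near background may pull a ratio towards 0 or make it large and unstable. The printed folds can thus be too small or too large, and the number of arrays limits the precision.

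The 29 gene lists, the size rule and the rule for named genes were fixed before the data were examined. The lists hold 647 entries, of which 572 were measured. Named genes were the 8 highest and the 8 lowest genes meeting the size rule in each comparison, up to 4 members of each list with the largest ratio in size, and up to 2 members that met the rule against the list's median. Other list members are named where stated. List medians were set against 10000 random lists of the same size drawn from all named genes. These were not matched on expression level, which the ratios do not hold, and the percentile describes these RNAs.

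The alternatives were median centring of each array, a least-squares estimate over the loop, 2-fold on the mean alone, 4-fold on both arrays, single probes, genes measured on all 6 arrays, each array left out, and a limma fit (version 3.58.1, R 4.3.3) with a dye term, which leaves 3 residual degrees of freedom among hybridisations and measures hybridisation error only. Reading the values as natural logarithms and leaving out genes with large dye effects were added after the data were seen. The calculations used Python 3.11.15 with pandas 2.3.3. The size rule was tested on simulated data for the testis and SVF arrays with 20935 probes. It called 0 of 20735 unchanged probes, 0 of 50 with a log2 change of 0.5, 39 of 50 with 1.5, 48 of 50 with 2.0 and 50 of 50 with 3.0. The limma fit, tested on simulated data of the same kind, called 10% of probes with a change of 0.5, 100% of those with 1.5 or more and 0.0241% of unchanged probes. The simulated noise was normal with the same SD for every probe of a comparison, estimated from these arrays. These rates therefore need not hold for the real arrays, where some probes vary far more than others.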

Results

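Transcript levels in testis, epididymis and the SVF of adipose tissue were compared on 6 arrays in 3 dye swaps, with 4 arrays carrying each tissue. Testis holds germ cells at all stages, with Sertoli and Leydig cells. Epididymis is the secretory duct in which spermatozoa mature. SVF holds mesenchymal progenitors, endothelial cells and immune cells. After the sign of the exchanged arrays was turned, the 2 orientations correlated across the 18550 named genes with Pearson's r of 0.88 for testis and SVF, 0.71 for epididymis and SVF, and 0.81 for epididymis and testis. Spearman's rho was 0.81, 0.57 and 0.75 in the same order. The median SD between the 2 arrays of a gene was 0.33, 0.37 and 0.35 on the log2 scale. The sum around the loop, which is 0 without error, had a median of 0.01 over all probes and an SD of 0.57 over named genes. For 92.4% of named genes this sum was at most 1 in size. A median near 0 over all probes does not show closure within a list. For late spermatid genes the median of epididymis over SVF was 1.69 directly and 1.44 by the least-squares loop estimate. The loop estimate also uses the direct ratio, so this gap understates the closure error of the list. The size rule was met in at least 1 comparison by 8731 genes (47.1%). Signs and folds below rest on a likely ratio direction and on reading the deposited logarithms as log2, neither of which the labels state. Medians on the single arrays are given below in the order of the first and the second array of a pair, wherever 1 of them differed in sign or by more than 1.5 times from the median of both.

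**Figure D1:**
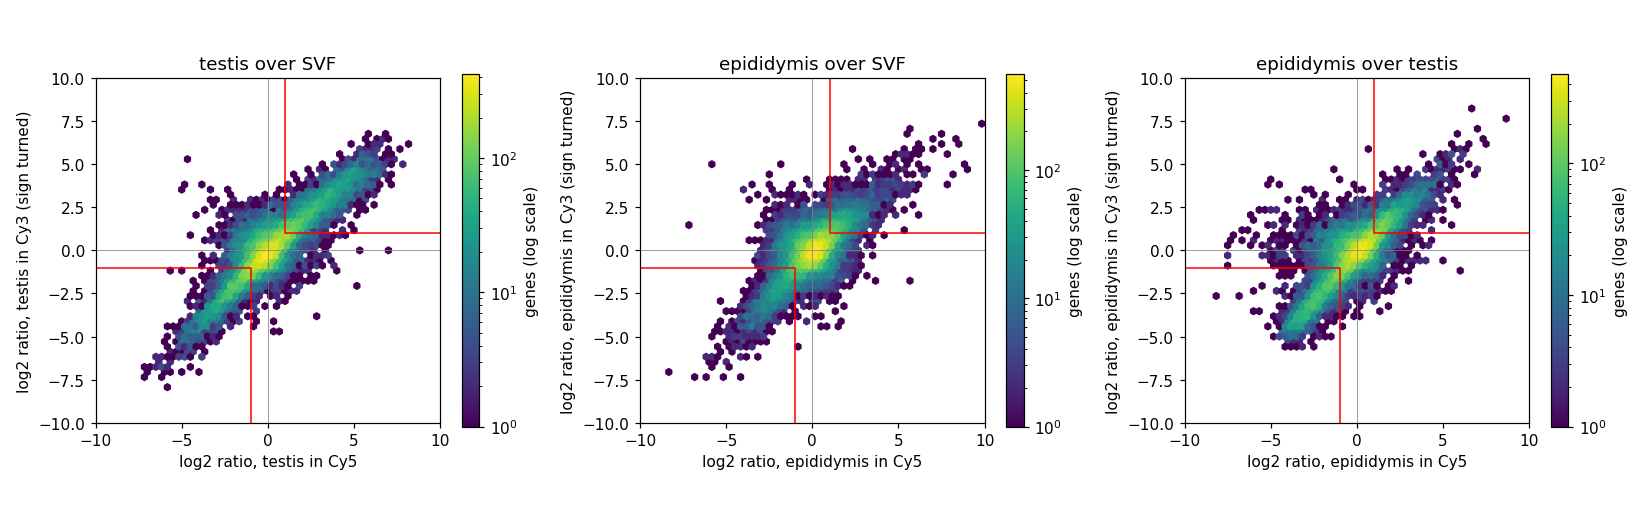
Log2 ratios of 18550 named genes on the 2 arrays of each dye swap, with the first tissue in Cy5 on the horizontal axis and in Cy3, sign turned, on the vertical axis. Colour gives the number of genes per hexagon on a log scale, and the red corners enclose genes at least 2-fold different in the same direction on both arrays; the epididymis and SVF panel is the most compact, with an SD of mean log2 ratios of 1.17 against 1.83 for testis and SVF.

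The first comparison asked which transcripts distinguish testis from SVF. Most late spermatid, meiosis and piRNA pathway genes were higher in testis, and most cytokine, early stress response, matrix and endothelial genes were higher in SVF. By the size rule 3838 genes (20.7%) were higher in testis and 2962 (16%) were higher in SVF. The 8 highest testis ratios belonged to Samt1, Spata46, 1700041C23Rik, Smc1b, 4930523O13Rik, 4930408G06Rik, Tex38 and 1700017N19Rik, with mean log2 ratios from 6.40 to 7.20. Samt1 was 147-fold higher in testis (7.20 ± 1.38). The cohesin subunit of meiosis, Smc1b, was 98.6-fold higher (6.62 ± 0.38). The 8 highest SVF ratios belonged to Cxcl10, Plau, Egr1, Ccl11, Ednrb, Prl2b1, Lyve1 and Nfkbiz. The interferon-induced chemokine Cxcl10 was 159-fold higher in SVF (log2 ratio of testis over SVF -7.32 ± 0.17). The urokinase gene Plau had a ratio of -6.98 ± 0.00, and the immediate early transcription factor Egr1 one of -6.94 ± 0.20.

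Among germ cell lists, 30 of 32 late spermatid genes were higher in testis, with a median log2 ratio of 3.75. The acrosomal gene Spaca1 stood at 5.77 ± 1.39, the fibrous sheath genes Cabyr and Akap4 at 5.37 ± 1.51 and 5.12 ± 0.83, and Crisp2 at 4.85 ± 1.25. Of 23 meiosis genes, 16 were higher (median 3.39), including the synaptonemal complex genes Sycp1 (5.58 ± 1.39) and Tex12 (5.49 ± 1.59). Of 19 genes of germline RNA and the piRNA pathway, 17 were higher (median 4.17), among them Piwil1 (5.76 ± 0.27), Dazl (5.56 ± 0.30) and Ddx4 (5.54 ± 0.03). All 3 medians were above those of 10000 random lists, and no member of these lists was higher in SVF. Of 14 testis-specific isozymes, 11 were higher in testis (median 2.85), with the glycerol kinase gene Gk2 64.2-fold higher and the phosphoglycerate kinase gene Pgk2 at 5.59 ± 1.13. The protamine and transition protein genes of sperm chromatin, chosen after their values were seen, varied more between arrays, with Prm1 at 2.87 ± 2.28, Tnp1 at 2.68 ± 2.27 and Tnp2 at 2.80 ± 1.59. Prm2, at 2.13 ± 2.16, did not meet the rule.

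Of 12 Leydig cell genes, 9 were higher in testis (median 2.05). The steroidogenic enzymes Cyp11a1, Hsd3b1 and Hsd17b3 stood at 4.74 ± 1.26, 4.25 ± 0.49 and 3.88 ± 1.26. Sult1e1, an estrogen sulfotransferase on the same list, was 21.5-fold higher in SVF. Of 19 Sertoli cell genes, 7 were higher in testis (median 0.46, with 0.28 and 0.83 on the single arrays), with Tsx at 5.58 ± 0.69, Aard at 4.29 ± 0.10 and the tight junction gene Cldn11 at 3.81 ± 0.34. The transferrin gene Trf was 23.5-fold higher in SVF. Of 17 spermatogonia genes, 3 met the rule, and these were Taf7l (4.24 ± 0.17), Tex19.1 (3.73 ± 1.62) and Uchl1 (1.64 ± 0.24), all higher in testis, against a list median of -0.08 that was 0.10 on the first array and 0.09 on the second.

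Immune lists differed in how many members were higher in SVF than in testis. Of 23 chemokine and cytokine genes, 20 were higher in SVF, with a median log2 ratio of testis over SVF of -4.05. Ccl11, an eosinophil chemokine, stood at -6.84 ± 1.39, Il6 at -6.43 ± 0.90 and the neutrophil chemokine Cxcl2 at -6.26 ± 0.14. Of 21 immediate early and stress genes, 17 were higher in SVF (median -4.07), including Egr2 (-6.42 ± 0.50), Fos (-6.39 ± 0.54) and Dusp1 (-5.70 ± 0.51). Of 22 macrophage genes, 18 were higher in SVF (median -3.77), with Ctss at -5.92 ± 0.44 and Cd163 at -5.13 ± 0.34, while Aif1 was 3.44-fold higher in testis. Of 17 genes of antigen presentation, 15 were higher in SVF (median -2.93), as were 13 of 22 T and NK cell genes (median -1.38), 7 of 13 B cell genes (median -1.21) and 6 of 14 mast cell and granulocyte genes (median -1.11). Examples were H2-Ab1 (-4.61 ± 0.76), Gzma (-5.31 ± 0.14), Ighm (-4.54 ± 0.24) and S100a9 (-5.45 ± 0.43).

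Among stromal lists, most matrix, mesenchymal progenitor and endothelial genes were higher in SVF. Of 29 extracellular matrix genes, 27 were higher in SVF (median -3.39), led by the collagen crosslinking enzyme Lox (-6.42 ± 0.15), Col5a2 (-5.62 ± 0.89) and decorin, Dcn (-5.03 ± 0.06). Of 21 mesenchymal progenitor genes, 18 were higher in SVF (median -2.61), with Cd34 at -5.17 ± 0.88 and Pdgfra at -4.88 ± 0.38. Endothelial genes were higher in SVF for 13 of 20 members (median -2.15), with the lymphatic marker Lyve1 at -6.70 ± 0.77. Of 22 adipocyte genes, 11 were higher in SVF (median -0.99), led by Fabp4 (-5.14 ± 1.04) and Lpl (-4.51 ± 0.35). The lipases Lipe and Pnpla2 were 4.02-fold and 3.43-fold higher in testis. Of 10 mesothelial genes, 5 were higher in SVF (median -1.40), with Upk1b at -4.94 ± 0.60. Of 16 smooth muscle and pericyte genes, 6 were higher in SVF (median -0.53), with Pdgfrb at -5.01 ± 0.19, and Actg2 was 12.3-fold higher in testis. Of 6 erythroid genes, 3 were higher in SVF (median -1.74, with -2.03 and -1.05 on the single arrays), with Hba-a1 at -2.60 ± 1.18, and Hemgn was 27.9-fold higher in testis.

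Among housekeeping lists, 19 of 35 cytoplasmic ribosomal protein genes were higher in SVF than in testis and none was lower (median -1.24, below all 10000 random lists). Of 24 X-linked housekeeping genes, 11 were higher in SVF (median -1.02, at percentile 0.04), and Cul4b was 4.70-fold higher in testis. Rps4x and Rpl10 belong to both lists and stood at -3.99 ± 0.76 and -3.66 ± 0.02. The X-linked Pdha1 stood at -2.66 ± 1.55. Oxidative phosphorylation genes went both ways, with 4 of 26 higher in testis and 2 higher in SVF (median 0.39, with 0.50 and 0.16 on the single arrays). Epithelial genes had 3 higher in testis, among them Epcam (2.64 ± 0.19), and 2 higher in SVF, Cldn7 and Krt18, of 21 (median -0.17, with -0.33 and -0.29 on the single arrays). Of 31 epididymal secretory genes, 12 were higher in testis and 3 in SVF (median 0.16, with 0.43 and 0.10 on the single arrays), with the protease inhibitor gene Eppin at 4.01 ± 0.16 and Cd52 at -2.71 ± 0.11. Of 25 beta-defensin genes, 8 were higher in testis (median 0.26, with 0.24 and 0.74 on the single arrays), with Defb19 at 5.67 ± 1.66. Of 12 clear cell and proton pump genes, 2 were higher in SVF (median -0.76, with -0.66 and -0.15 on the single arrays). Of 6 steroid receptor and androgen response genes 1 was higher in each tissue (Esr2 in testis, Fkbp5 in SVF), with a median of -0.18 that was -0.59 and 0.10 on the single arrays.

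The second comparison set epididymis against SVF. Most duct secretory and epithelial genes were higher in epididymis, and most cytokine, immediate early and matrix genes were higher in SVF. By the size rule 1890 genes (10.2%) were higher in epididymis and 1609 (8.7%) in SVF. Of these, 626 and 27 were at least 2-fold higher in testis than in both other tissues. At 4-fold on both arrays the larger count was in SVF, with 500 genes higher in epididymis and 675 in SVF. This pair of arrays was the least alike, and calling from a single array gave 3217 and 2670 genes without the second array and 3201 and 2707 without the first. The 8 highest epididymal ratios belonged to Pate6, Spint4, Rnase10, Defb12, Lcn9, Serpina1f, Defb38 and Ceacam10, from 6.74 to 8.56. Pate6 was 379-fold higher in epididymis (8.56 ± 1.58), and the Kunitz-type inhibitor gene Spint4 was 157-fold higher (7.29 ± 1.32). The 8 highest SVF ratios belonged to Il6, Tnf, Fos, Cxcl2, Ccl11, Has1, Lilrb4a and Il1b. Il6 was 215-fold higher in SVF (log2 ratio of epididymis over SVF -7.75 ± 0.93), Tnf was 134-fold higher (-7.06 ± 0.30), and the hyaluronan synthase gene Has1 stood at -6.30 ± 0.23.

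Of 31 epididymal secretory genes, 27 were higher in epididymis (median log2 ratio 3.64). Rnase10 stood at 7.24 ± 1.71, the lipocalin gene Lcn9 at 6.88 ± 2.93 and Serpina1f at 6.86 ± 2.72, and the protease gene Adamts5 was 8.35-fold higher in SVF. Of 25 beta-defensin genes, which encode antimicrobial peptides, 18 were higher in epididymis (median 4.10), with Defb12 at 7.10 ± 0.51, Defb38 at 6.77 ± 0.56 and Defb15 at 5.61 ± 0.09. Of 21 epithelial genes, 16 were higher in epididymis (median 2.80), including Epcam (4.38 ± 1.69), Cldn3 (4.37 ± 0.93) and the splicing factor gene Esrp1 (3.96 ± 0.66). These 3 medians were above those of 10000 random lists. Of 12 clear cell and proton pump genes, 3 were higher in epididymis (median 0.90), namely Foxi1 (2.32 ± 0.28), Car2 (1.71 ± 0.15) and Atp6v1e1 (1.37 ± 0.33). Among smooth muscle and pericyte genes, 4 of 16 were higher in epididymis and 2 in SVF (median 0.25), with Actg2 at 4.07 ± 0.33 and Pdgfrb at -3.62 ± 0.20.

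Of 32 late spermatid genes, 22 were higher in epididymis than in SVF (median 1.69), including the tektin gene Tekt2 (2.76 ± 0.54), Akap4 (2.73 ± 0.07) and Smcp (2.47 ± 0.84). The size rule was met toward epididymis by 9 of 19 germline RNA and piRNA pathway genes (median 1.24), with Mael at 2.60 ± 0.00 and Ddx4 at 2.27 ± 0.79. It was met by 6 of 14 testis-specific isozymes (median 0.99), with Pgk2 at 2.60 ± 0.86, and by 6 of 23 meiosis genes (median 0.64), with Syce1 at 2.23 ± 0.50 and Sycp1 at 2.19 ± 0.36. No member of these 4 lists was higher in SVF. Of 19 Sertoli cell genes, 5 were higher in epididymis and 2 in SVF (median 0.54, with 0.14 and 0.59 on the single arrays), with Clu at 2.78 ± 1.49 and Trf at -3.47 ± 0.69. Of 12 Leydig cell genes, Ptgds (3.50 ± 0.18) and Ces1d (1.61 ± 0.74) were higher in epididymis and Sult1e1 was higher in SVF (median 0.59). Of 17 spermatogonia genes, 3 were higher in epididymis (median 0.35, with -0.03 and 0.03 on the single arrays), with the GDNF receptor gene Gfra1 at 3.34 ± 0.70.

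Toward SVF, 21 of 23 chemokine and cytokine genes were higher than in epididymis (median -4.17). So were 17 of 21 immediate early and stress genes (median -3.46), with Fos at -6.67 ± 0.94, Egr1 at -5.84 ± 1.08 and Fosb at -5.20 ± 1.32. Among immune cell lists the counts higher in SVF were 18 of 22 macrophage genes (median -3.21), 10 of 17 antigen presentation genes (median -1.57), 13 of 22 T and NK cell genes (median -1.42), 5 of 13 B cell genes (median -1.02) and 8 of 14 mast cell and granulocyte genes (median -1.68). The mannose receptor gene Mrc1 stood at -4.74 ± 0.42, Cd74 at -3.91 ± 0.18 and the cytotoxic cell chemokine Ccl5 at -4.90 ± 0.20. Klrb1c and Foxp3 were 6.01-fold and 3.60-fold higher in epididymis, and so was lactoferrin, Ltf, at 6.35-fold. Of 29 matrix genes, 27 were higher in SVF (median -2.77), led by fibronectin, Fn1 (-4.95 ± 0.21). The counts were 12 of 21 for mesenchymal progenitor genes (median -2.35), with Cd248 at -4.05 ± 0.36, and 13 of 20 for endothelial genes (median -1.92), with the angiopoietin receptor gene Tek at -4.20 ± 0.16. Mesothelial genes were higher in SVF for 6 of 10 members (median -1.55) and erythroid genes for 3 of 6 (median -1.75), with 1 erythroid gene higher in epididymis.

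Of 22 adipocyte genes, 4 were higher in SVF and 2 higher in epididymis (median -0.14, at percentile 13.3, with -0.21 and -0.30 on the single arrays). Lpl stood at -3.35 ± 0.82 and Fabp4 at -3.01 ± 1.35, while Car3 was 2.82-fold and Scd1 2.44-fold higher in epididymis. None of 35 ribosomal protein genes met the rule (median 0.02, with -0.03 after median centring, -0.01 by the loop estimate, and 0.36 and -0.40 on the single arrays). Of 24 X-linked housekeeping genes, 5 were higher in epididymis (median 0.36), with Phf6 at 3.91 ± 0.16. Of 26 oxidative phosphorylation genes, 4 were higher in epididymis and Uqcrfs1 was higher in SVF (median 0.58). None of 6 steroid receptor and androgen response genes met the rule (median 0.28, with 0.10 and 0.26 on the single arrays).

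**Figure D2:**
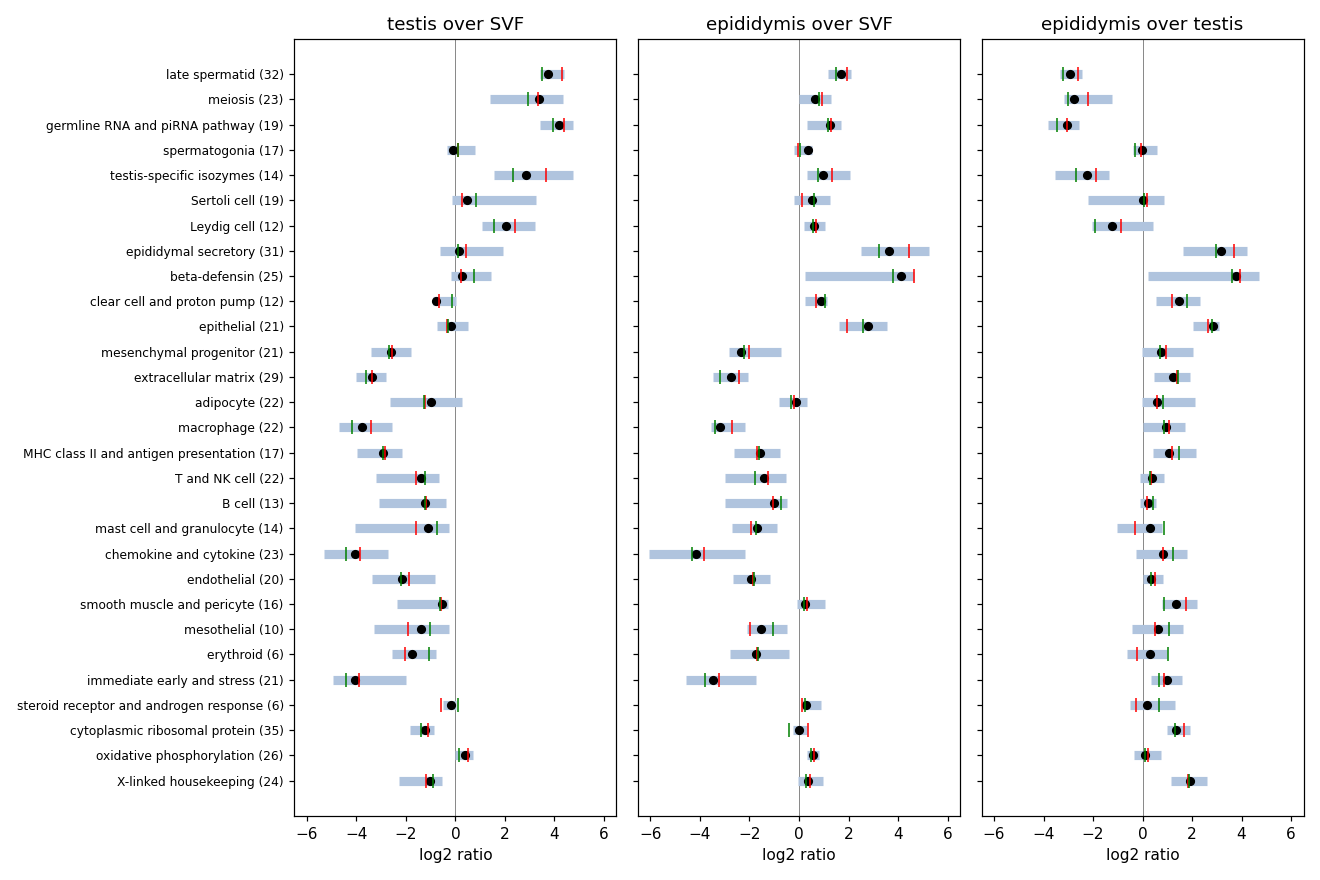
Median log2 ratio of each gene list (black points; list size in parentheses) in the 3 comparisons, with the quartiles of the list's genes as blue bars and the medians on the single arrays as red (first tissue in Cy5) and green (first tissue in Cy3) ticks. Late spermatid genes lie at 3.75 for testis over SVF, 1.69 for epididymis over SVF and -2.95 for epididymis over testis.

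The third comparison set epididymis against testis. Most duct secretory and epithelial genes were higher in epididymis, and most late spermatid, meiosis and piRNA pathway genes were higher in testis. By the size rule 2653 genes (14.3%) were higher in epididymis and 3342 (18.0%) in testis. The 8 highest epididymal ratios belonged to Pate6, Defb12, Hoxb6, Spint4, Cldn14, Ceacam10, Egr2 and Rnase10, from 6.11 to 8.19. Pate6 was 292-fold higher in epididymis (8.19 ± 0.90). The homeobox gene Hoxb6 was 121-fold higher (6.92 ± 0.06), the claudin gene Cldn14 114-fold (6.84 ± 0.96) and the immediate early gene Egr2 72.2-fold (6.17 ± 0.72). The 8 highest testis ratios were smaller in size, from -4.73 to -5.32, and belonged to 4930453L07Rik, 4933438K21Rik, 1700041C23Rik, 4930523O13Rik, Vwa5b1, 1700048O14Rik, Cypt15 and Iqub. The first of these, 4930453L07Rik, had an SD of 3.86 between its 2 arrays.

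Germ cell lists were higher in testis than in epididymis for 27 of 32 late spermatid genes (median log2 ratio of epididymis over testis -2.95), 17 of 23 meiosis genes (median -2.76), 16 of 19 germline RNA and piRNA pathway genes (median -3.07) and 10 of 14 isozymes (median -2.25). No member was higher in epididymis. Spaca1 stood at -4.38 ± 1.31, Smc1b at -4.62 ± 0.26, Gtsf1 at -4.49 ± 0.29, Piwil1 at -4.41 ± 0.16 and Gk2 at -4.39 ± 0.17. Of 12 Leydig cell genes, 6 were higher in testis (median -1.25, with -0.86 and -1.91 on the single arrays), with Hsd3b1 at -3.22 ± 0.11, and 3 were higher in epididymis, with Ptgds at 1.99 ± 0.15. Of 19 Sertoli cell genes, 7 were higher in testis and 3 in epididymis (median 0.01, with 0.18 and 0.05 on the single arrays and -0.01 after median centring), with Tsx at -4.19 ± 0.50, Nr0b1 at -3.21 ± 0.07 and the hedgehog ligand gene Dhh at -2.90 ± 0.35. Spermatogonia genes split into 2 higher in epididymis, Gfra1 (3.63 ± 0.29) and Etv5 (1.47 ± 0.40), and 2 higher in testis, Tex19.1 (-3.26 ± 1.80) and Taf7l (-3.08 ± 0.23), of 17 (median -0.04, with -0.05 and -0.31 on the single arrays).

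Toward epididymis, 24 of 31 epididymal secretory genes were higher than in testis (median 3.18), with Lcn9 at 5.74 ± 1.68 and Spink10 at 5.21 ± 0.36, while Wfdc15a was 13.5-fold higher in testis. The ratios of Spink10 did not close around the loop, at 3.28 ± 0.13 for testis over SVF and 5.48 ± 0.17 for epididymis over SVF. Its size over testis is therefore uncertain beyond the printed SD. The same holds for other genes with a small SD. Hoxb6 stood at -3.84 for testis over SVF and 4.40 for epididymis over SVF, against 6.92 for epididymis over testis. Of 25 beta-defensin genes, 16 were higher in epididymis (median 3.75), with Defb12 at 7.42 ± 1.03 and Defb10 at 5.84 ± 1.77, and Defb19 and Defb36 were 7.72-fold and 2.29-fold higher in testis. Of 21 epithelial genes, 18 were higher in epididymis (median 2.83), with the keratins Krt8 at 4.19 ± 0.35 and Krt18 at 3.78 ± 0.76. Of 12 clear cell and proton pump genes, 6 were higher in epididymis (median 1.46), with the proton pump subunit gene Atp6v0d2 at 3.56 ± 1.24 and Foxi1 at 3.29 ± 0.12, and Atp6v1b1 was 2.92-fold higher in testis. Of 16 smooth muscle and pericyte genes, 7 were higher in epididymis (median 1.35, with 1.74 and 0.86 on the single arrays), with Tagln at 3.70 ± 0.54 and Myh11 at 3.52 ± 0.63.

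Most stromal and immune lists had more genes higher in epididymis than in testis. The counts higher in epididymis than in testis were 14 of 29 for matrix (median 1.24), 8 of 21 for mesenchymal progenitors (median 0.74), 9 of 22 for macrophages (median 0.95), 8 of 17 for antigen presentation (median 1.05), 9 of 22 for adipocytes (median 0.57), 9 of 23 for chemokines and cytokines (median 0.84) and 8 of 21 for immediate early and stress genes (median 0.98). Toward testis they were 3 for immediate early and stress genes, 2 for macrophages, 2 for adipocytes, 1 for chemokines and cytokines, 1 for mesenchymal progenitors, and 0 for matrix and antigen presentation. Examples were Pdgfra (3.78 ± 0.38), Dcn (3.07 ± 0.16), Ctss (2.93 ± 0.04), B2m (3.41 ± 1.03), Scd1 (3.54 ± 0.24) and Ccl6 (3.07 ± 0.53). Klf4 was 10.4-fold and Aif1 9.71-fold higher in testis. Endothelial genes had 4 of 20 higher in epididymis and Flt4 higher in testis (median 0.34). Mesothelial genes had 4 of 10 higher in epididymis (median 0.61, with 0.51 and 1.08 on the single arrays), with Upk1b at 5.52 ± 0.21, and Muc16 was higher in testis. T and NK cell genes had 4 of 22 higher in epididymis (median 0.37). B cell genes had 1 of 13 higher in each tissue (median 0.21, with 0.18 and 0.41 on the single arrays), erythroid genes 1 of 6 in each (median 0.30), and mast cell and granulocyte genes 2 of 14 in each (median 0.32). On the single arrays the erythroid median was -0.24 and 1.02, and the mast cell and granulocyte median -0.32 and 0.86. Steroid receptor and androgen response genes had 2 of 6 higher in epididymis, with the androgen-responsive Fkbp5 at 2.68 ± 0.26 and Tmprss2 at 1.52 ± 0.17, and Esr2 was higher in testis (median 0.19, with -0.29 and 0.67 on the single arrays).

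X-linked housekeeping genes were higher in epididymis than in testis for 18 of 24 members (median 1.92), with Rpl10 at 3.96 ± 0.16, Phf6 at 3.87 ± 0.59 and Pdha1 at 3.20 ± 0.47, and Cul4b was 6.76-fold higher in testis. Ribosomal protein genes were higher in epididymis for 17 of 35 members (median 1.34), with Rpl22 at 3.35 ± 0.22. Both medians were above those of 10000 random lists. Oxidative phosphorylation genes had 4 of 26 higher in epididymis (median 0.11, with 0.22 and 0.08 on the single arrays), led by Cox7b (3.63 ± 0.31) and Ndufa1 (2.58 ± 0.21), and none higher in testis. These lists are not fully separate, with 1 of the 26 oxidative phosphorylation and 3 of the 24 X-linked housekeeping genes also on another list.

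Read over all 3 comparisons, in which each tissue's RNA enters 2 ratios, 2887 genes (15.6%) were at least 2-fold higher in testis than in both other tissues, 1289 (6.9%) in SVF and 805 (4.3%) in epididymis. Testis led for 27 late spermatid, 16 germline RNA and 15 meiosis genes. Epididymis led for 24 epididymal secretory, 16 beta-defensin and 15 epithelial genes. SVF led for 27 matrix, 19 chemokine and cytokine, 17 macrophage, 15 immediate early and stress, 12 endothelial, and 12 mesenchymal progenitor genes. Genes lowest in testis numbered 1478 and genes lowest in SVF 926, while 172 were lowest in epididymis.

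**Figure D3:**
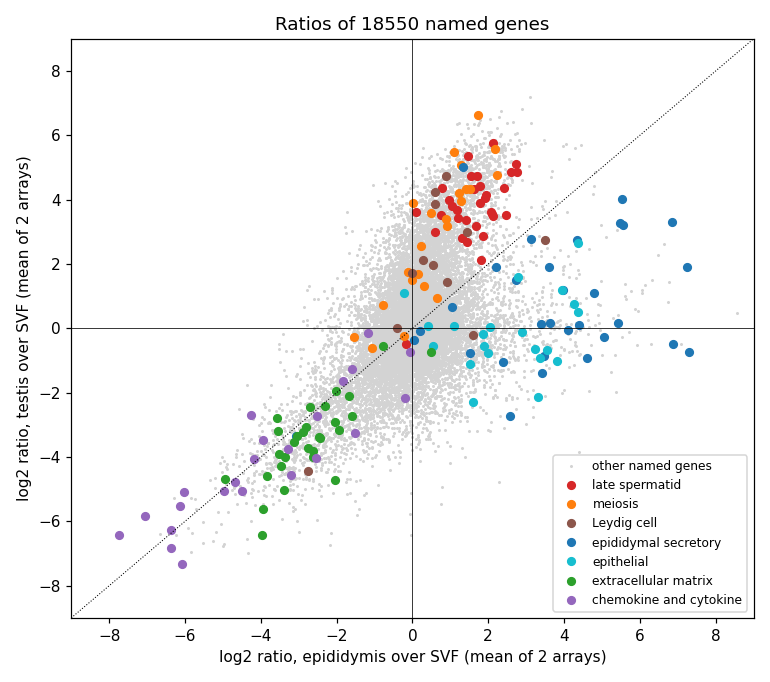
Mean log2 ratio of testis over SVF (vertical) against epididymis over SVF (horizontal) for 18550 named genes in grey, with 7 gene lists in colour; each point is a gene, the dotted line marks equal levels in testis and epididymis, and the SVF value is common to both axes. Late spermatid genes sit to the upper right of the origin (medians 3.75 and 1.69), epididymal secretory genes to the right (0.16 and 3.64), and matrix and cytokine genes at the lower left.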

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

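At 4-fold on both arrays the counts were 2245 higher in testis and 1411 in SVF for testis against SVF, 500 in epididymis and 675 in SVF for epididymis against SVF, and 926 in epididymis and 1781 in testis for epididymis against testis, with 1595, 287 and 579 genes leading in testis, epididymis and SVF; a stricter bound gives fewer by construction, and the larger count of the epididymis and SVF pair turned from epididymis to SVF. With 1 array left out, genes higher in epididymis than in SVF ranged from 3201 to 3217 and genes higher in SVF than in epididymis from 2670 to 2707. Calling from 1 array drops the condition on the dye-exchanged array, which raises counts by construction. The other alternatives left each of the 9 counts within 1.5 times its value, namely 1 array left out of the other pairs, median centring, the loop estimate, 2-fold on the mean, single probes, genes on all 6 arrays (which removed no gene), the limma fit, natural logarithms and the removal of genes with large dye effects, the last 2 chosen after seeing the data. The limma fit, which measures hybridisation error only, gave 4421 and 3445 genes for testis and SVF, 2503 and 1963 for epididymis and SVF, and 3195 and 3997 for epididymis and testis, at 2-fold and a Benjamini-Hochberg adjusted p under 0.05. Median centring moved the dye-swap means by at most 0.05 in log2, and the share of calls higher in epididymis against SVF from 54.0% to 51.0%. Of 87 list medians, 8 changed sign under centring, the loop estimate or the loss of 1 array (the spermatogonia, Sertoli, mast cell, erythroid, steroid receptor and ribosomal lists), and of 396 named gene means 2 did (Atp6v1g3 and Tmprss2 in testis against SVF); none of these was past 2-fold on both arrays. By more than the SD between arrays, the loop estimate moved 24 list medians and 97 gene means, centring 6 and 9, and single probes 6 and 0. Only 1629 of 18550 genes had 2 or more probes, and a gene with 1 probe keeps its value under single probes by construction. Each of the 87 list medians was also recomputed without each of its 2 arrays. Of these values 54 moved by more than the SD between arrays and 120 did not. A mean of 2 arrays cannot move by more than their SD when 1 is left out. A list median, taken over gene means, can do so, but it often lies close to the mean of its medians on the 2 arrays. The 120 therefore say little about stability. On a single array 24 of the 87 medians changed sign or differed by more than 1.5 times. The loop closure SD of 0.57 cannot change with centring. Signal over background was not analysed here. Precision is limited by 1 RNA sample per tissue, 2 arrays per comparison, and dye effects: 477 named genes (2.57%) had a mean dye effect above 1 in size, and 196, 286 and 262 genes were past 2-fold in opposite directions on the 2 arrays of the 3 pairs.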

Other observations

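The tests on luminal spermatozoa alone, on macrophages and on handling, and the gene families picked by symbol, were chosen only after the result was seen. All 4 Pate genes were higher in epididymis than in both SVF and testis, with Pate13 at 4.31 ± 0.58 and 4.58 ± 0.61 in log2. Among 7 Spink protease inhibitor genes, 5 were higher in epididymis than in SVF and 1 lower, with Spink12 at 5.92 ± 0.28 and Spink5 at 5.36 ± 0.16. Spink5 did not close around the loop, at -1.97 ± 0.20 for testis over SVF and 5.52 ± 0.03 for epididymis over testis. Spink2 was 52.3-fold higher in testis than in SVF. Of 36 Hox genes, 11 were higher in epididymis than in SVF and 1 lower, and 13 were higher in epididymis than in testis and 2 lower (Hoxa13 and Hoxc9). After Hoxb6, the largest ratios over testis were those of Hoxb5 (3.73 ± 0.29) and Hoxb2 (2.78 ± 0.47). Hoxa5 was 3.91-fold higher in SVF than in testis and 2.09-fold higher than in epididymis. Between testis and SVF, 20 of 24 Spata genes were higher in testis and none in SVF, 17 of 37 kinesin genes were higher in testis and 2 in SVF, and 49 of 111 Ccdc genes were higher in testis and 11 in SVF.

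Of 732 olfactory receptor genes, best known from the nasal epithelium, 28 (3.83%) met the size rule between testis and SVF, 6 (0.82%) between epididymis and SVF, and 25 (3.42%) between epididymis and testis. Probes for Sox2, Bmp8a and Rps6kc1 read below -3 on all 6 arrays as deposited (means -4.08, -4.99 and -4.03), whichever tissue carried Cy5. The dye half-differences of the 3 pairs correlated across all probes with r of 0.58, 0.55 and 0.51. The 4409 unnamed probes held 668 higher in testis and 366 higher in SVF.

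Late spermatid genes (22 of 32) and part of the other germ cell lists were higher in epididymis than in SVF on arrays that carried no testis RNA by design. The late spermatid median was 1.69 (single arrays 1.93 and 1.49, loop estimate 1.44). It lay above the bound of 0.5 set for spermatozoa or testis tissue in the epididymis preparation. The loop estimate also uses the direct ratio, so it is not a separate check. The list's medians in the other comparisons were 3.75 for testis over SVF and -2.95 for epididymis over testis. Their sum is smaller than the direct median of 1.69, although medians need not add exactly. The size of the late spermatid difference is therefore uncertain. The abundant Prm1 stood at 1.87 ± 0.40 and Prm2 at 1.81 ± 0.44, and none of the 32 genes is on another list. The meiosis median was 0.64 (single arrays 0.95 and 0.81, loop estimate 0.795). It lay above the same bound set for testis tissue rather than spermatozoa, though by little. Among genes at least 8-fold higher in testis than in SVF, the epididymis over testis ratio of late spermatid genes (median -3.15) exceeded that of meiosis genes (-3.45) by 0.30, with overlapping quartiles, so luminal spermatozoa alone cannot be told apart from a carry-over of several germ cell stages. All 1219 such genes had a median of -3.34 (45.9% higher in epididymis than in SVF), 4 Sertoli genes -2.69 (2 higher) and 2 Leydig genes -3.08 (0 higher), too few somatic genes to decide on whole testis tissue, and expression in the epididymis itself, which was not tested, may account for part.

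The reverse question was whether epididymal tissue had entered the SVF preparation, which could happen if the fat lay beside the epididymis; the labels do not say which depot was used. The epididymal secretory list had a median log2 ratio of SVF over testis of -0.16 (single arrays -0.43 and -0.10), at percentile 26.4 of random lists. This value lies under the bound of 0.5, and the rule set in advance counted such a value against carry-over. It is taken here to decide nothing, because the members went both ways, with 12 of 31 higher in testis and 3 in SVF. That reason was not part of the rule set in advance. Some members, such as Eppin at 4.01 ± 0.16 for testis over SVF, were high in testis, so a ratio over testis says little about their level in SVF. Against SVF itself, 27 of 31 secretory genes were higher in epididymis and 1 was lower (median 3.64). Of 25 beta-defensin genes, 18 were higher in epididymis than in SVF and 0 lower (median 4.10). None of these 25 was higher in SVF than in testis. These list values argue against RNA of the epididymal cells that express these genes as a large share of the SVF RNA. They were not set as a test in advance, and the folds can be too large where a signal lay near background. Whether a small amount of epididymal tissue, or tissue without these transcripts, had entered the SVF preparation stays open.

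Immediate early, stress, chemokine and cytokine genes held several of the largest SVF ratios. A larger share of macrophages is a candidate explanation, with their abundant gene Lyz2 at -2.72 ± 0.95 and Cd74 at -3.91 ± 0.18 for epididymis over SVF. The cytokine median for SVF over epididymis exceeded the macrophage median by 0.96, which lies between the bounds set for and against it, and activated macrophages also express these genes. Handling or digestion during SVF preparation is also open, but it has no test here, since the 15 of 21 immediate early and stress genes higher in SVF than in both other tissues are the pattern itself. Both cannot be told apart here from a difference of the tissue itself, because the SVF preparation and its cell mix coincide with the tissue on every SVF array.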
